A study of Saccharomyces cerevisiae with 29 samples.

How the data were processed

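Gene expression was measured in Saccharomyces cerevisiae on Agilent oligonucleotide arrays with 2 colours per array. The study's title concerns Ras acting on filamentous growth through protein kinase A. The labels name 4 strains: a wild type (WT), a strain labelled Ras*, a strain labelled tpk-w and a strain labelled Ras*tpkw. The labels do not spell out Ras* or tpk-w. Samples were taken at 20, 40 and 60 min in galactose (gal), and for WT also in glucose (glu). Each array held the RNA of 1 time in Cy5 and the 0 min RNA of the same series in Cy3, per the labels.

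Each of the 29 deposited array files holds the mean brightness and the local background of every spot in both channels as raw intensity, quantified by the authors with Feature Extraction 7.5.1. The same files hold a dye-normalized log10 ratio of Cy5 over Cy3, per the file headers after background detrending and a linear and LOWESS correction, and a 0 or 1 mark for spots well above background. The deposited series value table holds log2 ratios. Its columns equalled the deposited log10 ratio turned to log2 within 0.001 for 28 arrays, and had the opposite sign for 1 array.

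The raw intensities were processed in R 4.3.3 with limma 3.58.1. Background was corrected with normexp (offset 50), and ratios were normalized by loess within each array, with control spots and spots marked as non-uniform given no weight. Marked spots (1.03% of all) were left out, and the spots of a probe were averaged. An array holds 10807 spots, of which 10263 are for 6256 genes with 1 probe each. Genes well above background in either channel on at least 2 of 28 arrays were kept, which left 6210. Symbols came from the reference table of yeast genes, which named 5756 of the 6256. Levels at 0 min were compared in Cy3 after quantile scaling of mean brightness between arrays. Figures were drawn in Python 3.11.15.

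For depth, the median Cy3 signal of an array before background correction ran from 110.8 to 483.3 intensity units, and that of Cy5 from 159.6 to 816.4. Median signal over background ran from 4.82 to 18.6 in Cy3 and from 5.50 to 28.2 in Cy5. Between 5633 and 6141 genes per array were well above background in Cy3, and between 5678 and 6147 in Cy5. The number of arrays limits the precision.

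The study's design text calls repeat hybridizations technical replicates, so the arrays of a condition and time were averaged to 15 condition-by-time values, 3 times for each of 5 conditions. A limma model with condition and time as terms was fitted to these values, with moderated statistics and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. All p-values are two-sided. They measure spread over the 3 times, not between cultures, since each condition has 1 series with its own 0 min RNA. Errors beside log2 differences are standard errors of that fit (n = 3 times per condition). The comparisons were WT galactose against its 0 min, WT glucose against WT galactose, Ras* against WT, tpk-w against WT, Ras*tpkw against tpk-w, Ras*tpkw against Ras*, and the difference between the Ras* effects of both backgrounds, all in galactose except the second. A Ras* effect is the difference between a strain with Ras* in its label and the strain without it, each 1 series. Higher and lower between conditions refer to this ratio to the own 0 min, not to the level. A gene-specific dye effect cancels between conditions but not in WT galactose against its 0 min.

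Lists of genes were tested with camera at a preset correlation of 0.01, adjusted over 18 lists within a comparison. They were tested again with an estimated correlation and with the directional test of fry. The lists were cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, the general stress response (Msn2/Msn4), trehalose and glycogen, gluconeogenesis and the glyoxylate cycle, the TCA cycle and respiratory chain, glycolysis and fermentation, and hexose transport and glucose sensing. The others were the galactose (GAL) regulon, the Ras and PKA pathway, filamentous growth, amino acid biosynthesis (Gcn4), sulfur amino acids, G1 cyclins and G1/S genes, mating and pheromone response, meiosis and sporulation, and auxotrophic marker genes. Named genes were the 8 with the largest rise and the 8 with the largest fall among called genes that moved one way at all 3 times, the 3 members with the smallest p of each list that passed, and genes fixed beforehand whatever their p, among them RAS1, RAS2, TPK2, TPK3, BCY1, FLO11, GAL1 and HSP12. One gene of this fixed set is not reported here. The text names only part of the list members where lists gave over 30 genes. The tests, lists, naming rule and most alternatives were set before the data were examined.

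The pipeline was tested on simulated data with 200 changed genes among 6187. For Ras* against WT it called 56.7% of changes of 0.5 on the log2 scale, 82.1% of changes of 1 and 95.5% of changes of 2, with 5.45% false calls. For the difference of effects these shares were 14.9%, 56.7% and 92.4%, with 3.54% false calls. Each came from a single draw with noise independent over genes and times around a flat level. In the real series the times share a 0 min RNA and far more genes were called. These shares are therefore not the error rates of the counts below.

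The alternatives set at that time were median centring of each array without loess, the scanner software's ratio, the series value table, no background correction, other filters on dim probes, no time term, other variance settings, only the conditions of a comparison, each array as a sample (also with the replicate number, slide or image session as a block), and leaving out each condition and time or each replicate number. The alternatives added after the data were seen were exchanged time labels for a pair of arrays, 40 and 60 min only, each array as a sample with image session as a fixed block, and the first image session alone. Arrays were imaged in 3 sessions on 15 slides. The third session held every tpk-w array in the fit and no array of another condition in the fit, so tpk-w comparisons and that session cannot be told apart.

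One array, labelled WT galactose at 20 min, was left out because its labels disagree on which dye holds the 0 min RNA. It was added both ways as an alternative.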

Results

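The data were 29 arrays, of which 28 entered the comparisons. WT in galactose, WT in glucose, Ras* in galactose and Ras*tpkw in galactose had 6 arrays each, 2 at each of 20, 40 and 60 min. The tpk-w strain in galactose had 4 arrays, 2 of them at 40 min. Repeat hybridizations correlated across genes, which are not independent replicates, at 0.95 to 0.999, except those of Ras*tpkw at 20 min (0.843) and 40 min (0.844). Values are log2 ratios to the 0 min RNA of the same series, averaged to 3 time values per condition.

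Wild-type cells in galactose were compared with their own 0 min RNA, which shows what the galactose series did before any strain was compared. Genes of galactose use had the 3 largest rises. GAL7 (YBR018C), an enzyme of the Leloir pathway, was 142-fold higher (log2 7.14 ± 0.21, adjusted p = 8.13e-08). GAL2 (YLR081W), the galactose permease, was 118-fold higher in the fit, with its Cy5 spots saturated on every WT galactose array. Of the 8 genes of the GAL regulon, 6 rose, with a median of 3.15, and this list also passed with an estimated correlation (adjusted p = 0.00191). GAL10 rose by 4.60 ± 0.25, GAL3, the galactose sensor, by 3.19 ± 0.20, and GAL80, the repressor of the regulon, by 2.31 ± 0.07. GAL1 (YBR020W), the galactokinase, did not pass (0.03 ± 0.06, adjusted p = 0.781). Its 0 min Cy3 level (5.98) was near the floor, close to that of TPK3 in tpk-w (5.96), where TPK3 was not above background. GAL1 itself was marked above background on all 6 WT galactose arrays in both channels.

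In all, 615 of 6210 genes changed in WT galactose, 318 higher and 297 lower, and 36 by 2-fold or more. Other genes with large rises were HXT17 (3.45 ± 0.22), a hexose transporter, MTH1 (1.85 ± 0.08), a regulator of glucose transporter genes, and PGM2 (2.40 ± 0.50), the phosphoglucomutase that joins galactose use to glycolysis. Of 35 general stress genes, 8 rose and 27 did not pass (11 rose adjusted over the list alone), with a median of 0.59 (adjusted p = 0.379 with an estimated correlation). Of 21 trehalose and glycogen genes 7 rose, with a median of 0.49 (adjusted p = 0.379 with an estimated correlation). Of 22 genes of gluconeogenesis and the glyoxylate cycle 9 rose, with a median of 0.80 (adjusted p = 0.265 with an estimated correlation), among them YAT2 (1.17 ± 0.14) and SIP4 (0.67 ± 0.08). Of 105 ribosome biogenesis genes 18 fell (45 adjusted over the list alone), with a median of -0.55 (adjusted p = 0.405 with an estimated correlation), led by NSR1 (-1.76 ± 0.31) and NOG1 (-1.02 ± 0.21). Of 26 genes of RNA polymerases I and III 2 fell, with a median of -0.33 (adjusted p = 0.562 with an estimated correlation). Of 25 genes of the Ras and PKA pathway 4 rose, with a median of 0.16, or 0.24 with median centring (adjusted p = 0.0574 with an estimated correlation), including IRA2 (0.55 ± 0.07) and RIM15 (0.30 ± 0.05). Ribosomal protein genes fell in 34 of 137 cases, with a median of -0.16 (adjusted p = 0.253 with an estimated correlation), a call that ended with median centring (-0.001, adjusted p = 0.907). Of 23 genes of hexose transport and glucose sensing 6 rose, with a median of 0.10 (adjusted p = 0.253 with an estimated correlation) that turned to -0.08 with median centring (adjusted p = 0.488). At 40 and 60 min only, the stress, trehalose and hexose medians were 0.34, 0.26 and 0.03.

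The count of genes in this comparison depended on the times used and on the normalization. It was 187, 59 and 87 without WT galactose at 20, 40 and 60 min, 1691 without Ras* at 20 min, 403 without tpk-w at 40 min, 396 without Ras*tpkw at 40 min and 351 without the second repeats. Median centring gave 136 genes, with 75.7% of them higher against 318 of 615 after loess, and the scanner's ratio gave 269, with 39.8% higher.

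WT cells in glucose differed from WT cells in galactose in most of the transcriptome. Genes that make ribosomes were higher in glucose, and genes of respiration, gluconeogenesis, stress and galactose use were lower. None of these lists passed with an estimated correlation (adjusted p = 0.116 to 0.371). Of 6210 genes 4373 changed, 2118 higher and 2255 lower in glucose, and 1866 by 2-fold or more. The largest rises were those of TPO2 (YGR138C, 4.96 ± 0.26, adjusted p = 5.43e-07), a polyamine exporter, the RNA helicase DBP2 (4.78 ± 0.32), and HXT1 (4.72 ± 0.06), a low-affinity glucose transporter. IMD4, a gene of GTP synthesis, rose by 4.48 ± 0.27, AAH1, the adenine deaminase, by 4.39 ± 0.45, SAM1 by 3.99 ± 0.46, HXT3 by 3.85 ± 0.20 and DHR2 by 3.78 ± 0.42. The largest falls were those of GAL2 (228-fold lower in the fit, with saturated spots in WT galactose), GAL7 (-7.52 ± 0.30), ACS1 (-7.14 ± 0.83), the acetyl-CoA synthetase, and OM45 (-7.07 ± 0.92), a protein of the mitochondrial outer membrane. The high-affinity hexose transporter genes HXT7 (-6.95 ± 0.24) and HXT6 (-6.86 ± 0.24), the lactate permease gene JEN1 (-6.72 ± 0.18) and POT1 (-6.70 ± 0.65), a gene of fatty acid oxidation, also fell.

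In glucose all 105 ribosome biogenesis genes rose, with a median of 2.56, among them NOG2 (2.79 ± 0.21), MAK16 (2.77 ± 0.23) and UTP15 (2.35 ± 0.19). Of 26 genes of RNA polymerases I and III 25 rose, with a median of 1.82, including RPA49 (3.15 ± 0.29) and RPA34 (2.55 ± 0.23). Of 137 ribosomal protein genes 119 rose and 4 fell, with a median of 0.76 after loess and 2.44 with median centring. Of 50 genes of amino acid biosynthesis 30 rose and 8 fell, with a median of 0.52, such as ILV3 (1.84 ± 0.14) and ARO2 (0.99 ± 0.06), and a median of 1.09 with median centring. All 35 stress genes fell, with a median of -3.45, among them HSP26 (-5.02 ± 0.16), a small heat shock protein, and HSP12 (-5.12 ± 0.49). Of 21 trehalose and glycogen genes 20 fell, with a median of -2.55, such as the glycogenin gene GLG1 (-2.43 ± 0.10). All 22 genes of gluconeogenesis and the glyoxylate cycle fell, with a median of -4.56, and so did 46 of 47 genes of the TCA cycle and respiratory chain, with a median of -3.12, including CIT1 (-6.02 ± 0.30), KGD2 (-4.86 ± 0.16) and IDH1 (-4.36 ± 0.26). Of 8 GAL genes 7 fell, with a median of -4.47. Of 25 genes of the Ras and PKA pathway 15 fell and 5 rose, with a median of -0.67, and of 31 genes of meiosis and sporulation 20 fell and 5 rose, with a median of -0.22 that was -1.13 with the scanner's ratio.

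Counts adjusted over the list alone differed by at most 1 gene for these lists. With an estimated correlation none of the 11 lists passed, with adjusted p from 0.116 (GAL regulon) over 0.179 (ribosomal proteins, gluconeogenesis, Ras and PKA pathway, meiosis), 0.301 (stress, trehalose, TCA cycle), 0.357 (biogenesis) and 0.371 (polymerases) to 0.553 (amino acids). With each array as a sample, the calls of the Ras and PKA list (adjusted p = 0.0782) and the meiosis list (0.0777) ended. RAS2 fell by 2.34 ± 0.29, TPK2 by 1.47 ± 0.14 and BCY1, which encodes the regulatory subunit of protein kinase A, by 1.76 ± 0.15, while RAS1 (1.49 ± 0.29) and TPK3 (0.99 ± 0.12) rose. TPK2 and TPK3 encode catalytic subunits of that kinase. FLO11, a cell surface flocculin needed for filamentous growth, was at -0.93 ± 0.12 (adjusted p = 7.07e-05) after loess but at 1.15 with median centring. All 11 lists and all 53 named genes that passed kept 1 direction at all 3 times. For genes named for the largest rise or fall this was fixed, since the naming rule required it. Median centring gave 3672 genes, with the median of all genes at 0.11.

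The Ras* strain was compared with WT in the same medium, galactose, to see how the strains differed without a change of sugar. As in glucose, ribosome biogenesis genes were higher and stress, glycogen, respiratory and gluconeogenic genes lower. None of these lists passed with an estimated correlation (adjusted p = 0.409 to 0.422). Of 6210 genes 3305 changed, 1534 higher and 1771 lower, and 1174 by 2-fold or more. HXT2 (YMR011W), a high-affinity glucose transporter, had the largest rise (2.99 ± 0.42, adjusted p = 0.000605). It was followed by DHR2 (2.92 ± 0.42), CGR1 (2.91 ± 0.29), NSR1 (2.73 ± 0.44) and DBP7 (2.68 ± 0.41), all genes of ribosome assembly, AAH1 (2.66 ± 0.45), MCH5 (2.62 ± 0.65), a riboflavin transporter, and TRM11 (2.56 ± 0.28), a tRNA methyltransferase. The largest fall was that of TMA10 (YLR327C, -4.90 ± 0.45, adjusted p = 9.79e-05), followed by PGM2 (-4.38 ± 0.70), OM45 (-4.38 ± 0.92), RGI1 (-4.26 ± 0.34), STF2 (-3.99 ± 0.73), GLC3 (-3.44 ± 0.21), the glycogen branching enzyme, MHO1 (-3.41 ± 0.52) and BDH1 (-3.40 ± 0.67), the butanediol dehydrogenase.

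All 105 ribosome biogenesis genes rose in Ras*, with a median of 1.77 (adjusted p = 0.409 with an estimated correlation), and so did 25 of 26 polymerase genes, with a median of 1.53 (0.409). All 35 stress genes fell, with a median of -2.17 (0.409), among them USV1 (-3.25 ± 0.24), a stress transcription factor, and XBP1 (-0.80 ± 0.08). Of 21 trehalose and glycogen genes 19 fell, with a median of -1.85 (0.409), and of 22 genes of gluconeogenesis and the glyoxylate cycle 19 fell, with a median of -1.82 (0.409), including JEN1 (-1.82 ± 0.18) and its activator gene CAT8 (-1.73 ± 0.22), and a median of -1.06 with median centring. Of 47 genes of the TCA cycle and respiratory chain 40 fell, with a median of -1.14 (0.422), such as KGD2 (-2.92 ± 0.18), CIT1 (-2.13 ± 0.30) and NDI1 (-1.75 ± 0.32). With median centring the respiratory median was -0.41. That of other genes matched to ribosomal protein genes on brightness moved from -1.02 to -0.04. Numbers in brackets after a list median here are the adjusted p with an estimated correlation. Of 137 ribosomal protein genes 108 rose and 5 fell (111 and 6 adjusted over the list alone), with a median of 0.52 (0.409) after loess and 1.72 with median centring. Of 23 genes of glycolysis and fermentation 16 fell and 2 rose, with a median of -1.17 (0.422), led by the kinase genes HXK1 (-2.68 ± 0.42) and GLK1 (-3.32 ± 0.62), and median centring ended this call (-0.30, adjusted p = 0.451).

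In Ras*, the transcript of RAS2 (YNL098C, chromosome XIV, 439602 to 440570 in the reference annotation) rose by 1.80 ± 0.29 and that of RAS1 by 1.13 ± 0.29. TPK3 rose by 0.85 ± 0.12, BCY1 fell by 1.02 ± 0.15, TPK2 by 0.89 ± 0.14 and HSP12 by 1.84 ± 0.49. FLO11 was higher by 0.36 ± 0.12 (adjusted p = 0.0246). All 8 lists that passed kept their direction at all 3 times, but the size grew: the biogenesis median was 1.05 at 20 min, 2.11 at 40 min and 2.13 at 60 min, and the stress median -1.20, -2.72 and -2.56. The count was 2095 without Ras* at 40 min and 910 in a fit of these conditions alone. Values were alike in the first image session, which holds both conditions at 20 and 40 min (biogenesis 1.60, stress -1.91, 327 genes). They were alike too with each array as a sample and session as a block (1.89, -2.31, 4386 genes), where repeats of 1 RNA count as samples. Each array as a sample without that block gave 5143, but in another model that also held the tpk-w arrays, so the gap is not the effect of the block alone.

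**Figure D1:**
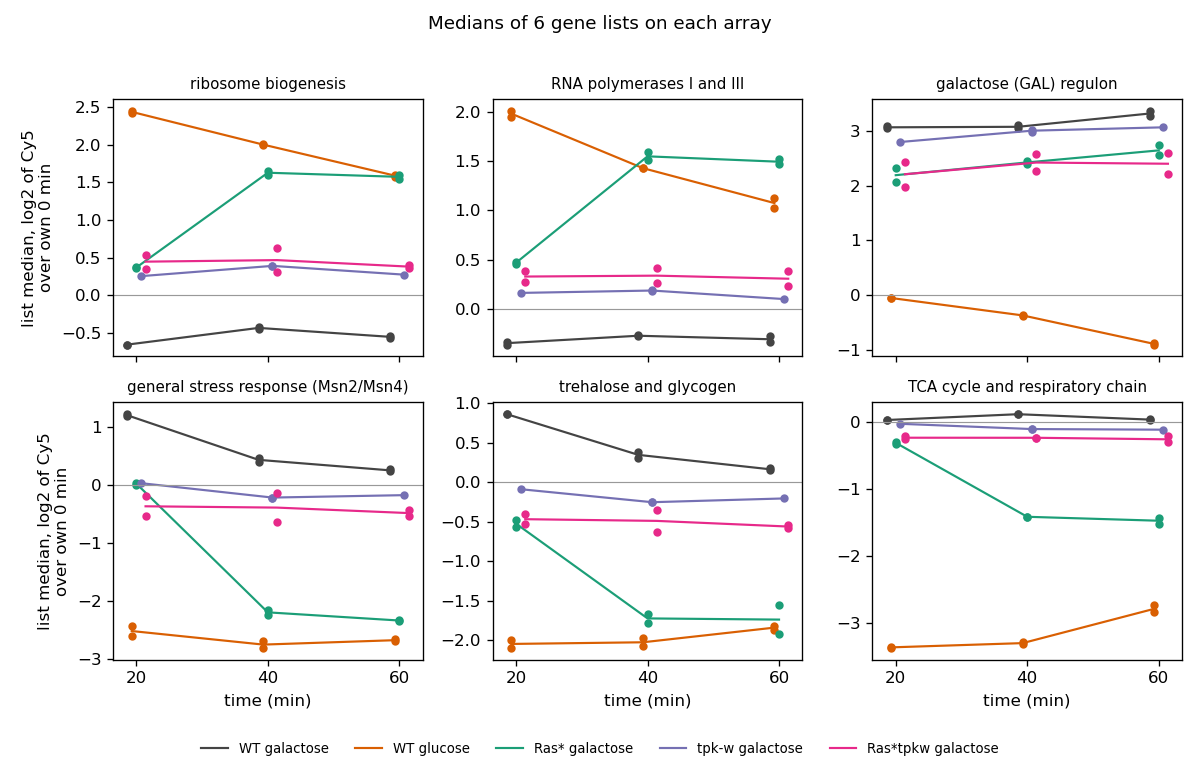
Medians of 6 gene lists (log2 of Cy5 over the 0 min RNA of the same series, y) against time in min (x), 1 point per array and a line through the mean of each time, coloured by condition. The biogenesis median in Ras* galactose rose from 0.38 at 20 min to 1.57 at 60 min, while that in Ras*tpkw galactose was 0.45 and 0.40.

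The effects of Ras* and of glucose were compared gene by gene, both against WT galactose. Across 6187 genes, which are not independent replicates, they correlated at r = 0.861, where noise in the shared WT galactose values alone gave 0.50 in 100 simulations. The covariance was 0.921, against 0.021 in these simulations, and r was 0.679, 0.864 and 0.784 at 20, 40 and 60 min. The simulated noise was the spread over times. It leaves out any error of the single WT galactose series and its 0 min RNA, which enters both effects. With separate WT galactose repeats for each effect r was 0.861, but these are technical replicates per the design text and do not remove such an error. With each condition only against its own 0 min r was 0.791, where gene-specific dye effects do not cancel. In all, 1294 genes rose in both comparisons, where the product of the counts over all genes gives 523.2, and 1521 fell in both, where it gives 643.1. In contrast, 36 genes rose in glucose and fell in Ras*, and 38 fell in glucose and rose in Ras*. The shared control adds to such overlaps.

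The tpk-w strain was compared with WT in galactose. The list medians of ribosome biogenesis and ribosomal protein genes were higher and those of stress and glycogen genes lower, with differences under those of Ras*. Most members of each list were not called, and no list passed with an estimated correlation (lowest adjusted p = 0.175). Of 6210 genes 338 changed, 178 higher and 160 lower, and 42 by 2-fold or more. The largest rises were those of NSR1 (2.39 ± 0.44, adjusted p = 0.0183), a nucleolar protein, DBP2 (2.16 ± 0.32), NIP7 (1.495 ± 0.34), URA7 (1.47 ± 0.34), ARX1 (1.39 ± 0.32), SPB1 (1.39 ± 0.32), DRS1 (1.37 ± 0.32) and NOG1 (1.34 ± 0.29). The largest falls were those of SPG4 (-1.81 ± 0.38, adjusted p = 0.0292), SPG1 (-1.29 ± 0.30), HXT7 (-1.20 ± 0.24), HXT6 (-1.18 ± 0.24), the glycogen synthase gene GSY1 (-1.18 ± 0.19), AI1 (-1.13 ± 0.26), GPM2 (-1.07 ± 0.19) and SDS24 (-1.06 ± 0.13). None of RAS1, RAS2, TPK2, BCY1, FLO11, GAL1 or HSP12 passed.

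Of 137 ribosomal protein genes 59 rose in tpk-w (95 adjusted over the list alone, with 2 lower), with a median of 0.31, or 0.56 with median centring (adjusted p = 0.175 with an estimated correlation), including RPL12A (0.72 ± 0.09) and RPS0B (0.65 ± 0.08). Of 105 biogenesis genes 14 rose (67 adjusted over the list alone), with a median of 0.87 (adjusted p = 0.457 with an estimated correlation). Of 26 polymerase genes none passed over all genes and 4 rose adjusted over the list alone, with a median of 0.42 (adjusted p = 0.563 with an estimated correlation). Of 35 stress genes 2 fell (7 adjusted over the list alone), XBP1 (-0.51 ± 0.08) and GPX1 (-1.002 ± 0.20), with a median of -0.77 (adjusted p = 0.457 with an estimated correlation). Of 21 trehalose and glycogen genes 4 fell (9 adjusted over the list alone), with a median of -0.70 (adjusted p = 0.457 with an estimated correlation). Of 22 genes of gluconeogenesis and the glyoxylate cycle 1 fell, SIP4 (-0.50 ± 0.12), with a median of -0.68 (adjusted p = 0.457 with an estimated correlation), a call that ended with median centring (-0.45, adjusted p = 0.0577). Of 23 genes of hexose transport 3 fell, HXT7, HXT6 and MTH1 (-0.53 ± 0.12), with a median of -0.10, or -0.45 with median centring and -0.25 with the scanner's ratio (adjusted p = 0.391 with an estimated correlation). Of 25 genes of the Ras and PKA pathway 1 fell, GPA2 (-0.44 ± 0.11), with a median of -0.14, or -0.24 with median centring (adjusted p = 0.273 with an estimated correlation). That call ended with the array of conflicting dye labels added as in the design text (adjusted p = 0.069), but not with it turned, as its GAL genes have it. The median of 24 G1 genes was 0.23, or 0.15 with median centring, with none called (adjusted p = 0.722 with an estimated correlation). The call of that list ended without WT galactose at 20 min (0.01), tpk-w at 40 min (0.18) or tpk-w at 60 min (0.21). It also ended with each array as a sample (adjusted p = 0.0615, and 0.0634 with the replicate block), with that array added as in the design text (0.145) and at 40 and 60 min only (0.268). With that array turned the G1 call stayed.

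The number of genes that changed in tpk-w depended on single time values, also those of conditions outside the comparison, which enter the estimated spread. It was 118, 1 and 59 without WT galactose at 20, 40 and 60 min, 87, 1 and 55 without tpk-w at those times, 606 and 167 without WT glucose at 20 and 40 min, 1340 without Ras* at 20 min, 182, 157 and 178 without Ras*tpkw at the 3 times, and 55 without the second repeats. Median centring gave 55 genes with 14.5% higher, against 178 of 338 after loess, the scanner's ratio gave 42, a fit of these conditions alone 2391, and every tpk-w array was imaged in a session that held no other array of the comparisons.

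Ras*tpkw was compared with tpk-w in galactose for the difference that goes with the Ras* label in the tpk-w background. RAS2 itself had the largest rise (2.91 ± 0.29, adjusted p = 0.00079), and ribosomal protein genes were higher, but no ribosome biogenesis gene was called. Of 6210 genes 560 changed, 295 higher and 265 lower, and 29 by 2-fold or more. Next to RAS2 the largest rises were those of UTR2 (1.68 ± 0.12), a cell wall crosslinking enzyme, SFG1 (1.16 ± 0.17), a transcription factor of pseudohyphal growth, YHP1 (1.09 ± 0.23), a cell cycle repressor, HNM1 (1.07 ± 0.15), the choline transporter, CYB5 (1.03 ± 0.26), ELO3 (1.01 ± 0.19) and RPS21A (0.99 ± 0.11). The largest falls were those of DIA1 (YMR316W, -2.33 ± 0.11, adjusted p = 9.55e-06), named for an effect on invasive growth, CIT2 (-2.15 ± 0.28), SPG1 (-1.91 ± 0.30), CMK2 (-1.75 ± 0.20), YBR287W (-1.72 ± 0.14), ACH1 (-1.60 ± 0.36), STP4 (-1.54 ± 0.11) and PCK1 (-1.50 ± 0.29), which encodes the key enzyme of gluconeogenesis.

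Of 137 ribosomal protein genes 105 rose in this background (123 adjusted over the list alone, with 1 lower), with a median of 0.53, a list that also passed with an estimated correlation (adjusted p = 0.0402). It was higher at all 3 times (0.57, 0.50 and 0.49, or 0.36 and 0.69 at 20 and 40 min with the time labels of a pair of Ras*tpkw arrays exchanged) and 0.43 with median centring. These are ratios to 0 min, where the median of these genes relative to WT galactose was -0.23 in tpk-w and -0.63 in Ras*tpkw, so a higher ratio need not be a higher level. Every tpk-w array was imaged in a session without Ras*tpkw arrays, so differences in this comparison cannot be told apart from that session. Of 105 biogenesis genes none was called, with a median of 0.15 (adjusted p = 0.0507). Of 21 trehalose and glycogen genes 4 fell, such as GLC3 (-1.04 ± 0.21), with a median of -0.37 (adjusted p = 0.60 with an estimated correlation). Of 22 genes of gluconeogenesis and the glyoxylate cycle 3 fell, CIT2, ADR1 (-0.58 ± 0.09) and PCK1, with a median of -0.49 (adjusted p = 0.60 with an estimated correlation). Of 23 glycolysis genes 2 fell, PYK2 (-0.74 ± 0.12) and CDC19 (-0.88 ± 0.21), with a median of -0.58 (adjusted p = 0.60 with an estimated correlation). Of 35 stress genes 1 fell, MSN4 (-0.44 ± 0.08), with a median of -0.30 (adjusted p = 0.794 with an estimated correlation), and that call ended without tpk-w at 40 min (-0.21) or 60 min (-0.27) or Ras*tpkw at 20 min (-0.11). Of 50 amino acid genes 3 rose and 1 fell, with a median of 0.20 (adjusted p = 0.60 with an estimated correlation), a call that ended with median centring (0.11, adjusted p = 0.947). HSP12 (-0.28 ± 0.49) and FLO11 (-0.12 ± 0.12) did not pass. The count was 1258 without Ras* at 20 min, 325, 242 and 255 without tpk-w at 20, 40 and 60 min, 237, 260 and 302 without Ras*tpkw at those times and 252 without the second repeats. Median centring gave 44 genes, the scanner's ratio 274 and a fit of these conditions alone 2930.

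Ras*tpkw was compared with Ras* in galactose, the comparison of the same Ras* label with and without tpk-w. The list medians of stress, glycogen and respiratory genes were higher in Ras*tpkw and that of ribosome biogenesis genes lower, with values between -0.20 and 0.12 at 20 min and larger ones at 40 and 60 min. Most members of these lists were not called, and no list passed with an estimated correlation (lowest adjusted p = 0.67). Of 6210 genes 1079 changed, 607 higher and 472 lower, and 238 by 2-fold or more. The largest rises were those of TMA10 (3.46 ± 0.45, adjusted p = 0.00377), PGM2 (3.04 ± 0.70), HPF1 (3.02 ± 0.53), STL1 (2.80 ± 0.59), a glycerol importer, GPD1 (2.75 ± 0.55), an enzyme of glycerol synthesis, SUE1 (2.39 ± 0.55), MHO1 (2.35 ± 0.52) and RGI1 (2.35 ± 0.34). The largest falls were those of HXT2 (-3.21 ± 0.42, adjusted p = 0.00377), MCH5 (-2.46 ± 0.65), PFK27 (-2.02 ± 0.50), YOR338W (-2.01 ± 0.59), PDE2 (-1.86 ± 0.33), the high-affinity cAMP phosphodiesterase, VID24 (-1.83 ± 0.52), CIT2 (-1.81 ± 0.28) and REX4 (-1.70 ± 0.42). RAS2 did not pass (0.45 ± 0.29, adjusted p = 0.233), and RAS1 was lower (-0.99 ± 0.29). The ratio of BCY1 to 0 min was higher in Ras*tpkw (0.98 ± 0.15) because it fell in Ras* (mean -0.905) and stayed at 0.073 in Ras*tpkw, where its 0 min level was already low.

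Of 105 biogenesis genes 29 fell in Ras*tpkw (39 adjusted over the list alone), with medians of 0.07, -1.11 and -1.18 at 20, 40 and 60 min. Of 26 polymerase genes 11 fell (19 adjusted over the list alone), with medians of -0.16, -1.21 and -1.23. Of 35 stress genes 6 rose (7 adjusted over the list alone), among them USV1 (2.16 ± 0.24), with medians of -0.20, 1.54 and 1.59. Of 21 trehalose and glycogen genes 8 rose (9 adjusted over the list alone), such as GAC1 (1.26 ± 0.13) and GLG1 (0.95 ± 0.10), with medians of -0.03, 1.04 and 1.07. Of 47 TCA cycle and respiratory genes 20 rose (41 adjusted over the list alone, with 1 lower), such as KGD2 (2.12 ± 0.18), with medians of 0.12, 1.34 and 1.25, a call that ended with median centring (0.18, adjusted p = 0.0558). Of 24 G1 genes 2 rose, CLN1 (1.19 ± 0.23) and SWI4 (0.44 ± 0.12), and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.48. Of 137 ribosomal protein genes 86 rose and 6 fell, with a median of 0.38 after loess, a ratio to 0 min levels that relative to WT galactose were 0.38 in Ras* and -0.63 in Ras*tpkw, so later levels need not be higher. With median centring the median turned to -0.74, and RPS0A, RPS16B and RPL37A turned from 0.64, 0.56 and 0.56 to -0.49, -0.70 and -0.61. Of 50 amino acid genes 10 rose, with a median of 0.15 after loess that turned to -0.33 with median centring. With a pair of Ras*tpkw time labels exchanged, the biogenesis medians at 20 and 40 min were -0.05 and -1.03, and the stress medians -0.14 and 1.24. The amino acid call also ended without WT galactose at 60 min (adjusted p = 0.053), Ras* at 20 min (0.505) or 40 min (0.0598), Ras*tpkw at 20 min (0.0947) or 60 min (0.0731), or the second repeats (0.122). It ended too with the scanner's ratio and the series value table (0.236), with genes well above background on every array (0.0752) and without a time term (0.0659). The same held with each array as a sample (0.141, with the replicate block 0.136, with session as a fixed block 0.29) and at 40 and 60 min only (0.616). The scanner's ratio gave medians of 1.25 for stress and 1.10 for trehalose and glycogen genes, against 0.77 and 0.68 after loess. The biogenesis median was -0.74 after loess and -1.34 with median centring.

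On the 2 slides that hold both strains at 60 min, the biogenesis medians were -1.09 and -1.23, the stress medians 1.43 and 1.57 and the ribosomal protein medians 0.27 and 0.44. In the first image session the biogenesis median was -0.54 and the stress median 0.52, and with each array as a sample and session as a block -0.88 and 0.90. The count was 596, 471 and 584 without WT galactose at 20, 40 and 60 min, 2099 and 540 without WT glucose at 20 and 40 min, 4001, 173 and 242 without Ras* at the 3 times, 553, 468 and 510 without tpk-w, and 207, 128 and 157 without Ras*tpkw. It was 911 with median centring, with 29.6% higher against 607 of 1079 after loess, 1467 with the scanner's ratio (48.1% higher), and 0 in limma fits of these conditions alone (1244 at an unadjusted p under 0.05) and of the first session alone (697).

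The Ras* effect in the WT background was then tested against that in the tpk-w background. By list median, ribosome biogenesis genes had a higher Ras* effect in the WT background and stress and glycogen genes a lower one, but with an estimated correlation none of these lists passed (adjusted p = 0.566), and 23 of 35 stress genes were not called. Of 6210 genes 936 had effects that differed, 455 with a higher and 481 with a lower value in the WT background, and 452 by 2-fold or more. Positive values below mean a higher Ras* effect in the WT background. The largest were those of HXT2 (3.12 ± 0.59, adjusted p = 0.0163), NSR1 (2.75 ± 0.62), AAH1 (2.58 ± 0.64), DHR2 (2.53 ± 0.59), CGR1 (2.51 ± 0.41), HMT1 (2.48 ± 0.48), TOD6 (2.42 ± 0.35), a repressor of ribosome biogenesis genes, and BUD22 (2.34 ± 0.50). The lowest were those of TMA10 (-4.49 ± 0.63, adjusted p = 0.0077), PGM2 (-3.94 ± 0.99), STF2 (-3.77 ± 1.03), RGI1 (-3.51 ± 0.48), MHO1 (-3.29 ± 0.74), CTT1 (-3.15 ± 0.90), the cytosolic catalase, HPF1 (-3.15 ± 0.74) and NCE102 (-3.03 ± 0.53).

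Of 105 biogenesis genes 74 had a higher Ras* effect in the WT background (102 adjusted over the list alone), with a median of 1.64, and so had 13 of 26 polymerase genes (23 adjusted over the list alone), with a median of 1.31. Of 35 stress genes 12 had a lower effect (28 adjusted over the list alone), with a median of -1.60, and so had 12 of 21 trehalose and glycogen genes (15 adjusted over the list alone), with a median of -1.44. The polymerase list too had an adjusted p = 0.566 with an estimated correlation. Of 22 genes of gluconeogenesis and the glyoxylate cycle 2 had a lower and 1 a higher effect, with a median of -1.36 (adjusted p = 0.819 with an estimated correlation), and the call ended with median centring (-0.80, adjusted p = 0.783) and without Ras* at 40 min (-0.93) or tpk-w at 20 min (-1.23). Of 47 TCA cycle and respiratory genes 4 had a lower effect, with a median of -0.94 (adjusted p = 0.819 with an estimated correlation), and with median centring the call ended (-0.11, adjusted p = 0.829) with a test direction opposite to its median. Among ribosomal protein genes 6 had a higher and 10 a lower effect, with a median of -0.05 and a mean of 0.01 (adjusted p = 0.961) after loess, but a median of 1.297 with median centring. The biogenesis, polymerase, stress and trehalose medians kept their signs at all 3 times, but the biogenesis median was 0.84 at 20 min, where Ras*tpkw against Ras* was at 0.07 and tpk-w against WT at 0.93, and RAS2 did not pass (-1.11 ± 0.41, adjusted p = 0.0807).

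Across 6187 genes the Ras* effects of both backgrounds correlated at r = 0.413, with 0.565, 0.304 and 0.327 at 20, 40 and 60 min (0.47 and 0.408 at 20 and 40 min with the Ras*tpkw labels exchanged), and their SD over genes was 0.819 in the WT and 0.292 in the tpk-w background. In all, 196 genes rose in both, where the product of the counts gives 72.87, and 194 fell in both, where it gives 75.57. The count of genes with differing effects was 304, 84 and 271 without WT galactose at 20, 40 and 60 min, 1735 and 539 without WT glucose at 20 and 40 min, 3567, 139 and 350 without Ras*, 130, 208 and 220 without tpk-w, and 326, 66 and 177 without Ras*tpkw at the 3 times. Median centring gave 1257, with the median of all genes at -0.19. The planned addition of the array with conflicting dye labels, gave 505 as the design text has it and 688 turned. A fit of these 4 conditions alone gave 1426.

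**Figure D2:**
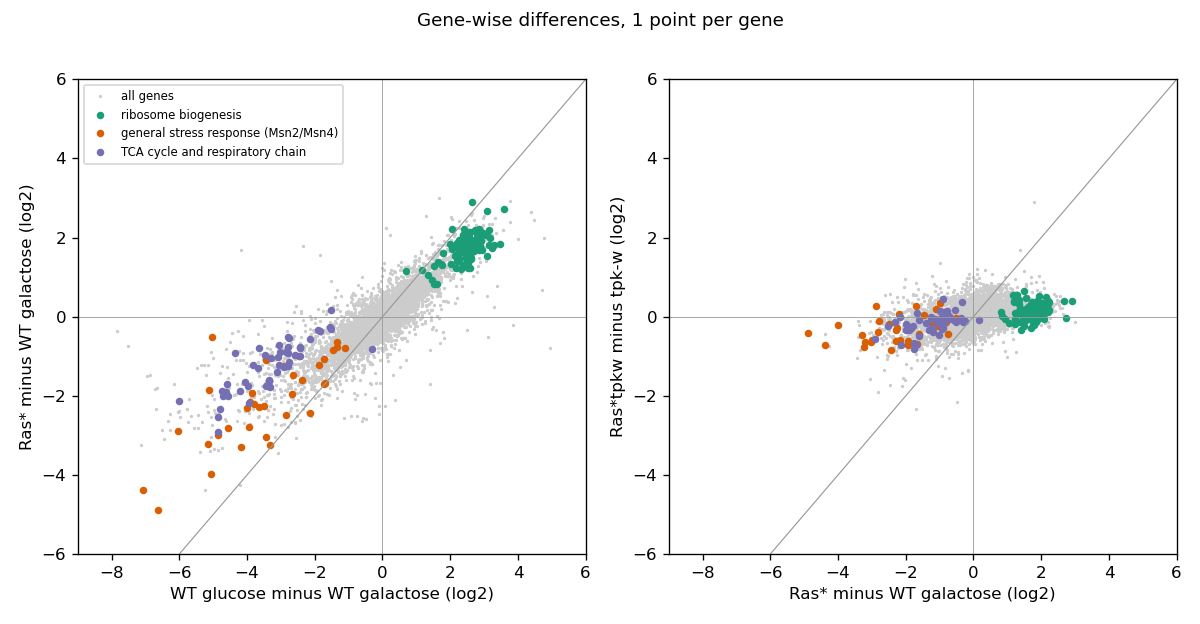
Log2 differences, 1 point per gene, for Ras* minus WT galactose (y) against WT glucose minus WT galactose (x) on the left, and for Ras*tpkw minus tpk-w (y) against Ras* minus WT galactose (x) on the right, with 3 gene lists in colour and the line of equal values. Points on the left follow a line (r = 0.861), and those on the right spread less on the y axis (SD 0.292) than on the x axis (SD 0.819).

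Levels in the 0 min RNA of each series, taken before the later times, differed in the genes of the pathway itself. TPK3 was not above background on any of the 4 tpk-w or 6 Ras*tpkw arrays, in either channel, whereas it was above background in Cy3 on all 6 arrays of each other condition. Ratios of TPK3 between times in these strains therefore carry no information, and the differences of TPK3 against Ras* (-0.78) and between the effects (0.78) rest on the Ras* and WT values alone. The BCY1 difference between the effects (-1.23) likewise rests mainly on Ras* and WT, since its ratio to 0 min was -0.129 in tpk-w and 0.073 in Ras*tpkw. BCY1 at 0 min differed from WT galactose by -2.55 in tpk-w and by -3.04 in Ras*tpkw, and TPK2 was higher by 0.72 and 0.86 (SD between arrays at most 0.13). RAS2 at 0 min was higher by 0.78 in Ras*, 1.12 in Ras*tpkw and 0.30 in tpk-w, and by 0.70 and 0.21 in the latter strains with array medians subtracted. Among marker genes, URA3 was higher by 2.26 in Ras* and 4.21 in Ras*tpkw, and LEU2 by 3.10 and 3.30. The SD here is between arrays that share 1 RNA, so no test between cultures can be had.

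**Figure D3:**
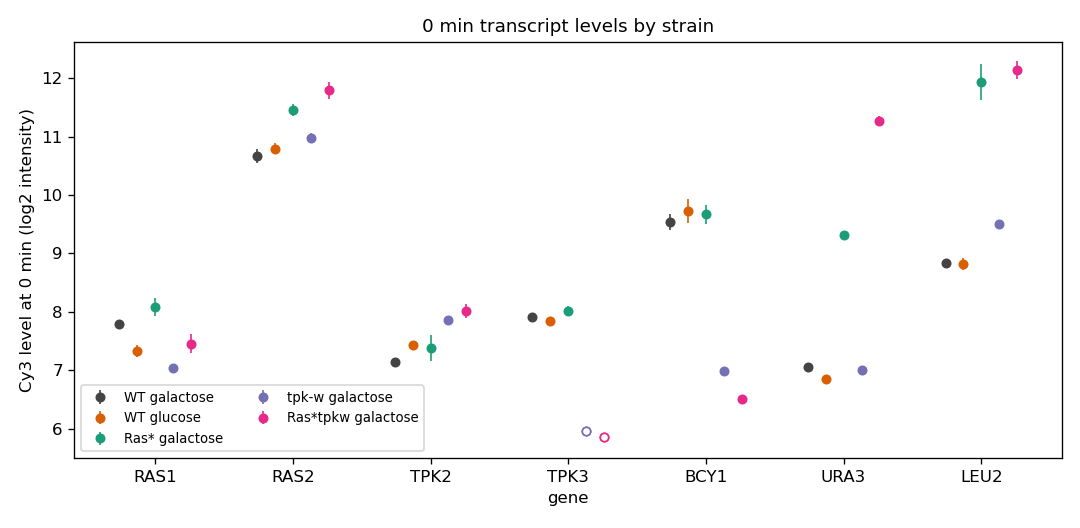
Cy3 level at 0 min (log2 intensity after quantile scaling, y) of 7 genes (x) in the 5 series, as the mean of 6 arrays (4 for tpk-w galactose) with bars for the SD between arrays. Open circles mark a gene above background on no array of the series: TPK3 in tpk-w and Ras*tpkw.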

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

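Of the tests below, the comparison within slides, the RAS2 test, the check of biogenesis genes with median centring in Ras*tpkw against Ras*, the tests of the tpk-w session at 20 min and in tpk-w against WT and the test of exchanged labels were chosen after the results were seen. The other tests were set before.

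A difference between groups drew attention to the Ras* effect, which was tested in the WT against the tpk-w background. It differed for 936 genes. By list, the median difference was 1.64 for ribosome biogenesis, 1.31 for RNA polymerases I and III, -1.60 for general stress, -1.44 for trehalose and glycogen, -1.36 for gluconeogenesis and the glyoxylate cycle and -0.94 for the TCA cycle and respiratory chain, where median centring gave -0.11. Among genes it was 1.42 for RAS1, 0.78 for TPK3 and -1.23 for BCY1. The largest differences were 3.12 for HXT2, 2.75 for NSR1, 2.58 for AAH1, 2.53 for DHR2, 2.51 for CGR1, 2.48 for HMT1, 2.42 for TOD6 and 2.34 for BUD22. The lowest were -4.49 for TMA10, -3.94 for PGM2, -3.77 for STF2, -3.51 for RGI1, -3.29 for MHO1, -3.15 for CTT1, -3.15 for HPF1 and -3.03 for NCE102. The TPK3 value carries no information on the tpk-w strains, where that gene was not above background. The BCY1 value rests mainly on Ras* and WT, since in tpk-w and Ras*tpkw its 0 min level was low and its ratio flat (-0.129 and 0.073).

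Of 100 drawn splits of the 12 condition-by-time values into 4 groups of 3, 2 gave as many genes as the real 936, the real one included. The 3 values of a real group are times of 1 series that share a 0 min RNA, so they cannot be exchanged freely with others. The count of splits therefore cannot exclude chance. Nor does it test chance in the difference of effects alone, since most splits mix Ras* with WT values, whose difference is large, and 97 of the others gave 0. The highest other split gave 1785, above the real count, and it kept all 3 Ras* values and all 3 WT galactose values together, which points to that difference as a structure of the samples. For each comparison of 3 values against 3 there are only 10 splits, which is too few for a share under 0.05. In each of them 1 split, the real one, gave as many genes. The real counts were 4373 for glucose against galactose (highest other 0), 3305 for Ras* against WT (1), 338 for tpk-w against WT (0), 560 for Ras*tpkw against tpk-w (0) and 1079 for Ras*tpkw against Ras* (1).

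The first pattern weighed is the smaller Ras* response of ribosome biogenesis genes in the tpk-w background. At 60 min the separate image session of the tpk-w arrays does not account for all of it, since on slides that hold Ras* and Ras*tpkw side by side the median difference was at most -1.09, but at 20 min Ras*tpkw against Ras* was at 0.074, so the difference of 0.84 there rests on tpk-w against WT and cannot be told apart from that session. A weaker RAS2 induction is argued against by a RAS2 difference that was higher by 1.11 in the tpk-w background. That value did not pass and includes the tpk-w arrays of the separate session. In Ras*tpkw against Ras*, which needs no tpk-w array, RAS2 did not pass either. Within-array loess as the source of its direction is argued against by a median of 1.64 after loess and 2.25 with median centring, though the size moved. Over all times the part from tpk-w against WT (0.87) cannot be told apart from the session, because no session holds both conditions among the arrays compared, and the only WT array of that session, with conflicting dye labels, gave a tpk-w difference at 20 min of 0.69 when turned, as its GAL genes and the series value table have it, and -0.22 as in the design text, and is a single array. The strain difference named in the design, and differences between single cultures, stay open as untested explanations.

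The second pattern is that the list median of ratios to 0 min was higher for ribosomal protein genes and lower for ribosome biogenesis genes in Ras*tpkw than in Ras*. Of 137 ribosomal protein genes 86 rose and 6 fell, and of 105 biogenesis genes 29 fell, with a biogenesis median of 0.07 at 20 min. Neither list passed with an estimated correlation (adjusted p = 0.67 for both). Slides or sessions are argued against by a ribosomal protein median of at least 0.27 within slides at 60 min. The normalization may be the source of the ribosomal protein part, since that median turned to -0.74 with median centring, and other genes matched on brightness, 3 per ribosomal protein gene, had a median of 0.755 after loess and -0.003 without it. Of the 200 brightest genes, 79 encode ribosomal proteins, so their own change enters the loess curve, and the direction of that list stays open. The biogenesis median was -0.735 after loess and -1.34 with median centring, which argues against loess as the source of its direction, though the size moved.

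The third pattern is a pair of repeats. The arrays of Ras*tpkw labelled 20 and 40 min correlated more strongly across times than within a label, 0.986 and 0.984 against 0.843 and 0.844, a margin of 0.14 that no other condition shows. A candidate explanation is that the time labels of the first repeats at 20 and 40 min were exchanged. No biological explanation was tested. The exchange leaves each mean over times as it is but not the values at single times, such as the ribosomal protein medians of Ras*tpkw against tpk-w, which become 0.36 and 0.69 at 20 and 40 min in place of 0.57 and 0.50.

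A signal also appeared in an array outside the comparisons, the WT galactose array at 20 min with conflicting dye labels. Its median log2 ratio of Cy5 over Cy3 for the GAL regulon was -3.13, against 3.06 in the other arrays of that condition and time, and GAL7 was at -7.78 against 7.15 and GAL2 at -7.63, which goes against the dyes of the design text. Its correlation with them across genes was -0.484.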

How the results depend on the processing

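Of the alternatives below, exchanged time labels, 40 and 60 min only, each array as a sample with image session as a fixed block, the first session alone, and the list totals with the scanner's ratio were chosen after the data were seen. The comparison of glucose with galactose stayed within 1.5 times its 4373 genes under every alternative run, from 3340 in the first session alone to 5518 with each array as a sample and slide as a random block. No background correction, the filters on dim probes, no time term, trend and robust variance, and exchanged labels changed no count by over 1.5 times. Where a count moved, the cause was not tested. Fits with fewer values or fewer conditions have fewer degrees of freedom, which does not account for the counts that rose in such fits. Each array as a sample counts repeats of 1 RNA as samples. Leaving out Ras* at 20 min raised every count, also in comparisons without Ras*, because the spread is estimated over all conditions.

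Median centring gave 55 genes for tpk-w against WT, 44 for Ras*tpkw against tpk-w and 136 for WT galactose against 0 min. The scanner's ratio and the series value table each gave 42, 274 and 269. Fits of a comparison's conditions alone gave 910 for Ras* against WT, 2391 for tpk-w against WT, 2930 for Ras*tpkw against tpk-w, 0 for Ras*tpkw against Ras* (1244 at an unadjusted p under 0.05 in limma) and 1426 for the difference of effects. No such fit was made for WT galactose against 0 min, where the time term leaves no degrees of freedom. With each array as a sample the counts were 5143 for Ras* against WT, 3650 for tpk-w against WT, 3588 for Ras*tpkw against tpk-w, 4882 for Ras*tpkw against Ras*, 4493 for the difference of effects and 4211 for WT galactose against 0 min. In that order, again with each array as a sample, they were 5134, 3620, 3568, 4863, 4479 and 4177 with the replicate number as a block, 5198, 3762, 3705, 4910, 4554 and 4322 with slide as a random block, and 5160, 3761, 3717, 4900, 4555 and 4305 with image session as a random block. Over 66 pairs of conditions and times, the deviations of equally numbered repeats correlated at -0.838 to 0.467 (median -0.004), with 10 pairs over 0.1. An effect of the number common to all conditions was thus not seen. Some equally numbered repeats shared a slide, such as WT glucose and WT galactose at 60 min, so the median cannot exclude pairing within slides.

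The array with conflicting dye labels, added as in the design text, gave 129 genes for tpk-w against WT, 505 for the difference of effects and 247 for WT galactose against 0 min. Turned, as its GAL genes have it, it gave 211, 688 and 414, and all 57 pairs of list and comparison that passed kept their calls. At 40 and 60 min alone the counts were 1283 for tpk-w against WT, 1013 for Ras*tpkw against tpk-w, 3935 for Ras*tpkw against Ras*, 3379 for the difference of effects and 1549 for WT galactose against 0 min. With each array as a sample and image session as a fixed block Ras*tpkw against Ras* gave 3720. That fit left out the tpk-w arrays and had condition and time as separate terms. The fit that gave 4882 had a mean for each condition and time, so the gap between these counts is not the effect of the block alone. The first session alone gave 327 for Ras* against WT and 0 for Ras*tpkw against Ras* (697 at an unadjusted p under 0.05).

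Leaving out 1 condition and time or 1 replicate number gave 2095 to 4388 genes for Ras* against WT, 1 to 1340 for tpk-w against WT, 237 to 1258 for Ras*tpkw against tpk-w, 128 to 4001 for Ras*tpkw against Ras*, 66 to 3567 for the difference of effects and 59 to 1691 for WT galactose against 0 min. The lowest came without Ras* at 40 min for the first, WT galactose or tpk-w at 40 min for the second, Ras*tpkw at 20 min for the third, Ras*tpkw at 40 min for the next pair, and WT galactose at 40 min for the last. Each highest value came without Ras* at 20 min.

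Of 126 pairs of list and comparison 57 passed. With fry 45 passed, with median centring 68, with each array as a sample 57, with the scanner's ratio 65, with 40 and 60 min alone 64, and with an estimated correlation 2. Directions that turned did so with median centring alone, except those of the G1 list. The medians then were -0.74 for ribosomal proteins and -0.33 for amino acids in Ras*tpkw against Ras*, and in the difference of effects 1.297 for ribosomal proteins, -0.11 for the TCA cycle (by test direction), 0.43 for glycolysis, 0.35 for amino acids and -0.46 for mating genes. They were 0.12 for the TCA cycle in tpk-w against WT, 0.41 for mating and 0.41 for meiosis genes in Ras*tpkw against tpk-w, and -0.27 for mating and -0.25 for meiosis genes in WT galactose against 0 min. Of these, ribosomal proteins and amino acids in Ras*tpkw against Ras* and the TCA cycle in the difference of effects had passed after loess. The G1 median was 0.008 in tpk-w against WT and 0.287 in WT galactose against 0 min without WT galactose at 20 min, and -0.18 in WT galactose against 0 min without WT galactose at 60 min. Among named genes, median centring turned FLO11 in glucose against galactose to 1.145 and, in Ras*tpkw against Ras*, RPS0A to -0.49, RPS16B to -0.70 and RPL37A to -0.61. It turned JEN1 in the difference of effects to 0.089.

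The correlation of the Ras* and glucose effects was 0.861, 0.791 against the own 0 min and 0.852 with median centring, within the SD of 0.093 over times. With array medians of Cy3 subtracted, 0 min differences from WT galactose were 0.21 for RAS2 in tpk-w and 0.70 in Ras*tpkw. They were 0.56 for TPK2 in Ras* and 0.84 in tpk-w, and -2.62 for BCY1 in tpk-w. For TPK3 in tpk-w the value was -1.98, which rests on a level not above background, so the size of that difference is not measured. Every gene has 1 probe, so the planned choice of the brightest probe was not run. Signal over background limits genes near the floor, such as TPK3 in the tpk-w strains.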

Other observations

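Some lists did not pass or went both ways. Genes of filamentous growth, 29 measured, had medians between -0.05 (Ras* against WT, 7 rose and 8 fell) and 0.11 (glucose against galactose, 12 rose and 9 fell; Ras*tpkw against Ras*, 5 rose and 0 fell), and the list passed with camera in none of the 7 comparisons. With directional fry it passed in Ras*tpkw against Ras* alone (higher, adjusted p = 0.0338). The mixed test of fry counts changes both ways and does not set a list against other genes. It passed in glucose against galactose (adjusted p = 5.29e-08), Ras* against WT (6.68e-05) and Ras*tpkw against tpk-w (1.78e-09). It also passed in Ras*tpkw against Ras* (0.000536) and the difference of effects (0.0207), but not in tpk-w against WT (0.42) or WT galactose against 0 min (0.113). Sulfur amino acid genes, 24 measured, had medians from -0.09 to 0.10 and passed in none with camera or directional fry. With mixed fry they passed in glucose against galactose (adjusted p = 5.29e-08), Ras* against WT (0.00143) and Ras*tpkw against Ras* (0.0145). Mating and pheromone genes, 24 measured, had medians from -0.05 to 0.04 and passed in none after loess with camera or directional fry. Genes of meiosis and sporulation had a median of -0.07 in Ras*tpkw against Ras*, with 3 called higher. Auxotrophic marker genes, 8 measured, had medians from -0.12 to 0.13 and passed in none with camera or directional fry. Hexose transport genes in Ras* against WT went both ways, with 4 higher and 7 lower and a median of -0.03.

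The 0 min RNA of the series differed in the medians of several lists. Relative to WT galactose at 0 min the ribosome biogenesis median was 0.37 in Ras*, -0.42 in tpk-w and -0.43 in Ras*tpkw. The median of ribosomal protein genes was 0.38 in Ras*, -0.23 in tpk-w and -0.63 in Ras*tpkw. G1 genes had medians of -0.79, -0.37 and -0.45 in Ras*, tpk-w and Ras*tpkw. Genes of gluconeogenesis and the glyoxylate cycle had medians of 0.45 in tpk-w and 1.02 in Ras*tpkw. The WT glucose series differed from WT galactose at 0 min too, though both are labelled WT. Its medians were -0.16 for biogenesis, 0.12 for ribosomal protein, 0.04 for G1 and 0.42 for gluconeogenesis and glyoxylate genes. They were 0.58 for stress, 0.78 for TCA cycle and respiratory and 0.89 for glycolysis genes. Of these WT glucose medians, those of G1 (percentile 69.8) and gluconeogenesis genes (86.8) lay within the 5 to 95% range of 10000 random lists matched on size and level. The ribosomal protein median lay under that range (0.304 to 0.443), so these genes were low against others of like level. Ratios of each series start from its own 0 min levels. Each is 1 RNA, so no difference between strains can be tested.

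GAL1 was at 5.98 to 6.07 on the log2 scale of Cy3 in all conditions, close to TPK3 in the strains where TPK3 was not above background. The ratio of GAL1 to 0 min in WT galactose was 0.03 while GAL7 and GAL10, its neighbours on chromosome II, rose. GAL1 was above background in Cy3 on all 6 arrays of WT galactose and of Ras*, but on 1 of 4 tpk-w arrays. With array medians subtracted, its 0 min level relative to WT galactose was 0.90 in Ras* and 0.23 to 0.35 in the other conditions. In Ras* galactose the ratios to 0 min at 20 and 40 min correlated across genes at 0.54, and those at 40 and 60 min at 0.964. Ras* and Ras*tpkw correlated at 0.72, 0.58 and 0.544 at 20, 40 and 60 min, or at 0.74 and 0.612 at 20 and 40 min with the Ras*tpkw time labels exchanged.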
